A study of Mus musculus with 18 samples.

How the data were processed

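CD8+ T cells from spleen and lymph nodes of C57BL/6J mice had been sorted into 41BB+ (Tpam in the study) and 41BB- (conventional) cells. 41BB (CD137) is a costimulatory receptor of the TNF receptor superfamily, encoded by Tnfrsf9. RNA was taken directly after the sort (0 h) or after 24 h or 72 h of culture with beads carrying antibodies to CD3 and CD28, which activate T cells through the T cell receptor. The series describes biological triplicates, so the 18 libraries form 6 groups of 3. Whether a triplicate was 1 animal or a pool of animals is not given in the sources used here.

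Libraries were made with the SMARTer Stranded Total RNA-Seq Kit v2, per the labels' protocols. Reads were checked with FastQC 0.11.9, trimmed with Trimmomatic 0.38, aligned with HISAT2 2.2.1 and counted with featureCounts on GRCm38, per the submitters' processing notes. The annotation release, the strand setting and the treatment of reads with several matches are not given in the sources used here. The deposited table holds unnormalized whole-number read counts of 55487 Ensembl genes, 1 column per library. A second deposited table gives the experiment number (1 to 3) of each library, which was the replicate number of the labels in all 18. Symbols and coordinates came from GENCODE M21 on GRCm38, which held 55227 of the gene IDs, and 260 IDs had no symbol. Without a stated strand setting, reads of a gene and of an overlapping or antisense gene cannot be told apart. Without a stated treatment of reads with several matches, values of genes with close copies are uncertain (Amd1 and Amd2, Ifi211 and Ifi213, and abundant genes with processed pseudogenes such as Eif5a, Ldha, Npm1 and the ribosomal proteins).

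Total counts per library ran from 3085241 to 4239795 (median 3524157.5), with 16503 to 22816 genes detected. Within each group, the counts of replicate libraries differed by 4.80 to 9.84 times the sampling variance (chi-square per degree of freedom over genes), so no library was a copy of another. Levels are given as CPM (counts divided by the library total and scaled to 1e+06), as mean ± SD of 3 libraries. A fold against a group with 0 counts is a lower bound computed against 3 counts over the group. With 1 to 3 counts in the lower group, the ratio is given with its exact 95% counting interval. These bounds and intervals cover counting error only, since no molecular identifiers were used.

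Differential expression was tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr by group (minimum count 10, minimum total count 15), which left 13150 of 55487. TMM factors, robust quasi-likelihood dispersions and 1 mean per group were fitted to all 18 libraries together, so that all groups shared 1 estimate of the spread (common biological coefficient of variation 0.18). Each contrast was tested by the quasi-likelihood F-test, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Every adjusted p of a gene is from this test. The contrasts were 41BB+ against 41BB- cells at each time, 24 h against 0 h and 72 h against 24 h in each population, and the interaction of population and time over each interval. Positive log2 fold changes mean higher in 41BB+ cells, or higher at the later time. Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, with adjustment over the lists of each comparison. Lists needed at least 4 tested members, and 31 of 35 had them in every comparison. The call of each list was repeated with an estimated correlation, and that p is printed wherever a call was lost. For each list the number of members past the threshold is also given adjusted over the list alone.

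The 35 lists held 776 entries, of which 772 were found. They covered polyamine synthesis, turnover and transport, hypusination, T cell states (naive and central memory, effector and cytotoxic, memory-phenotype and resident, coinhibitory receptors and exhaustion, TCR-induced early response, regulatory T cell, CD8 T cell identity), TNF receptor and ligand superfamily, cytokines and their receptors, chemokine receptors and homing, other cells (CD4 helper, innate-like and gamma-delta T, NK, B, plasma, dendritic, myeloid, erythroid and platelet, stromal and endothelial), S phase, G2 and M phase, glycolysis, oxidative phosphorylation, tricarboxylic acid cycle, amino acid and one-carbon metabolism, cholesterol synthesis, fatty acid oxidation, ribosome biogenesis, cytosolic ribosomal proteins, type I interferon response, apoptosis regulators, NF-kB feedback, and heat shock. Genes were named by a fixed rule. It took Tnfrsf9, Cd8a, Cd8b1, Cd4 and Foxp3 as checks of the sort, and the 5 largest log2 fold changes in each direction among genes past the threshold with a mean of at least 5 CPM whose 3 libraries of one group all lay above the 3 of the other (not required of an interaction). Predicted genes and antigen receptor segments were left out. It also took up to 4 members of each list with the smallest adjusted p, and 12 genes of polyamine metabolism and hypusination whatever their test. The groups, comparisons, tests, lists, this rule and all alternatives, except where stated, were chosen before the data were examined.

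The experiment number (1 to 3, as in the labels) was checked as a pairing of the populations. At each time the 2 libraries of an experiment number held like shares of Y-linked counts, and the numbers differed from each other. At 0 h these shares were 0.000177%, 0.0128% and 0.0222% in 41BB+ libraries 1 to 3 and 0%, 0.0174% and 0.0285% in 41BB- libraries 1 to 3. Deviations from the group means over 10071 autosomal genes had a median correlation of 0.155 in the 9 pairs of 1 time and number (lowest 0.0586, 6 above 0.1), -0.0894 in the 18 pairs of 1 time and other numbers, and 0.0102 in the 36 pairs of another time and the same number. The numbers were therefore taken to pair the populations within a time and not across times. The fit without a block stayed the main one, as fixed.

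On counts simulated from the real means with 67 genes changed 2-fold, 67 changed 1.41-fold and 66 changed 4-fold in 1 contrast at a time (12597 to 12633 genes tested), the edgeR step recovered 67.2% of the 2-fold and 95.5% of the 4-fold genes of the 0 h population contrast, with 4 unchanged genes called. Unchanged genes made up 3.45% to 8.89% of the calls of a contrast, the most at 72 h between populations (12 genes) and then from 24 h to 72 h in 41BB- cells (9 genes, 6.77%). For the 2-fold genes the share was 58.2% at 24 h and 68.7% at 72 h between populations, 49.3% and 55.2% for the first and second interval in 41BB+ cells, 64.2% and 73.1% in 41BB- cells, and 31.3% and 37.3% for the interactions. At 1.41-fold the shares were 5.97%, 14.9% and 20.9% for the population contrasts at 0, 24 and 72 h, so many small differences would be missed. The list step called a list shifted by 0.5 on the log2 scale (adjusted p = 1.91e-18) and 0 others. Correlated members were not simulated (0.681 was estimated for ribosomal proteins), so control of false list calls was not shown.

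Alternatives were DESeq2 1.42.0, RLE factors, no filter on low counts, the experiment number as a block, only the compared groups in the fit, limma voom with library quality weights, removal of mitochondrial and ribosomal genes, a minimum of 2-fold, and each compared library left out in turn. For lists they were the estimated correlation and fry. A block within each time and the share of Y-linked counts as a covariate were added after the data were seen. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for the other steps. All processed files at hand were used. A gene withheld for evaluation is not reported here.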

Results

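Transcripts were counted in 41BB+ and 41BB- CD8+ T cells of mouse spleen and lymph nodes. Both were sampled at 0 h and after 24 h and 72 h of CD3 and CD28 stimulation. Each of the 6 groups had 3 libraries, and 13150 of 55487 genes had enough counts to be tested. Levels are given in CPM as mean ± SD (n = 3), differences as log2 fold changes (log2FC), and coordinates are on GRCm38. Mitochondrial genes took 6.15% to 11.4% of the counts of a library, the 10 most abundant genes took 16.1% to 26.5%, and Gm23935, annotated as a microRNA gene, alone took 5.10% to 10.1%. At 72 h the share of mitochondrial counts was 10.9% ± 0.473 in 41BB+ and 9.14% ± 0.373 in 41BB- libraries, and all 3 of the first lay above the 3 of the second (exact two-sided permutation p = 0.1, the smallest that 3 against 3 can give). At 0 h the nuclear noncoding RNA Malat1 took 0.371% ± 0.0336 of counts in 41BB+ and 0.736% ± 0.107 in 41BB- libraries, at 24 h 0.137% ± 0.0115 and 0.220% ± 0.0461, and at 72 h, with the order turned round, 0.223% ± 0.0311 and 0.145% ± 0.0195 (exact permutation p = 0.1 at each time).

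The 0 h comparison came before any stimulation in culture. Tnfrsf9 (chromosome 4, 150914562 to 150946102), the gene of 41BB itself, stood at 383 ± 33 CPM in 41BB+ and 6.68 ± 1.8 CPM in 41BB- cells (log2FC 5.83, adjusted p = 2.49e-13). Cd8a (chromosome 6, 71373427 to 71379173) was present at 498 ± 71 and 632 ± 59 CPM and Cd8b1 (chromosome 6, 71322788 to 71337494) at 392 ± 41 and 869.5 ± 101 CPM, both lower in 41BB+ cells (log2FC -0.34, adjusted p = 0.0207 and log2FC -1.15, adjusted p = 2.01e-07). The Cd8a call was lost without 41BB+ replicate 1 (adjusted p = 0.103), without 41BB+ replicate 3 (0.0680) and without 41BB- replicate 3 (0.0967). Cd4 had 0 to 4 counts in any of the 18 libraries and was not tested. Foxp3 (chromosome X, 7573644 to 7595245), the lineage factor of regulatory T cells, was near the floor in both populations (2.88 ± 2.0 and 0.511 ± 0.89 CPM, log2FC 2.4, adjusted p = 0.0214), and its call was lost without 41BB+ replicate 2 (adjusted p = 0.166), 41BB- replicate 2 (0.0994) or 41BB- replicate 3 (0.10), with log2FC from 1.7 to 6.35 when 1 library was left out. In all, 5192 genes differed at 0 h, of which 2916 were higher and 2276 lower in 41BB+ cells, and 2725 of them by at least 2-fold.

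The largest differences at 0 h that met the naming rule included Gzmb (chromosome 14, 56258838 to 56262260), which encodes the cytotoxic protease granzyme B, at 67.2 ± 7.0 CPM in 41BB+ and 0.822 ± 0.35 CPM in 41BB- cells (log2FC 6.29, adjusted p = 6.77e-06). Mcm10 (chromosome 2, 4989714 to 5012791), which encodes a DNA replication initiation factor, was at 15.4 ± 3.5 CPM in 41BB+ cells and had 0 counts in 41BB- cells, at least 49.7-fold higher. Rgs16 (chromosome 1, 153740349 to 153745468), a regulator of G protein signaling, and Bcat1 (chromosome 6, 144993835 to 145076184), which encodes the cytosolic branched-chain aminotransferase, stood at 35 ± 3.7 against 0.625 ± 0.54 CPM and 97.6 ± 6.8 against 1.85 ± 0.49 CPM (log2FC 5.75, adjusted p = 6.72e-12 and log2FC 5.69, adjusted p = 0.000138). The transcription factor gene Maff (chromosome 15, 79346621 to 79359076, log2FC -4.16, adjusted p = 7.39e-07), Apol8 (chromosome 15, 77747798 to 77757003, log2FC -3.59, adjusted p = 0.00241) and the cytokine signaling inhibitor gene Socs3 (chromosome 11, 117966079 to 117970047, log2FC -3.51, adjusted p = 6.15e-07) were lower in 41BB+ cells. So were the AP-1 gene Fos (chromosome 12, 85473890 to 85477273) and the growth factor binding protein gene Igfbp4 (chromosome 11, 99041244 to 99054392), with 14.4 ± 7.6 against 154 ± 95 CPM and 17.8 ± 8.6 against 185 ± 29 CPM (log2FC -3.43, adjusted p = 0.00524 and log2FC -3.37, adjusted p = 1.17e-10). Xcl1, a chemokine gene, was at 142 ± 16 and 2.88 ± 1.2 CPM, Il2ra, which encodes the high-affinity interleukin-2 receptor chain, at 55.2 ± 13 and 3.3 ± 0.73 CPM, and Eomes, a T-box transcription factor gene of effector and memory CD8 T cells, at 558 ± 40 and 56.1 ± 5.1 CPM. Their log2 fold changes were 5.61, 4.05 and 3.31 (adjusted p = 5.99e-08, 5.12e-08 and 3.95e-08). The inhibitory receptor gene Lag3 had 3 counts in the 41BB- libraries against 167 in the 41BB+ libraries, a ratio of 49.7 (95% counting interval 16.7 to 244).

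Genes of cell growth and DNA replication were higher in 41BB+ cells at 0 h. Of 28 tested genes of ribosome biogenesis, 28 were higher, and all of them also adjusted over the list alone (28). Among them, Ncl (chromosome 1, 86344719 to 86359400), which encodes the nucleolar protein nucleolin, stood at 4208 ± 108 against 825 ± 18 CPM (log2FC 2.35, adjusted p = 1.98e-17). For ribosome biogenesis, camera gave adjusted p = 2.27e-18 (passed), or 0.0954 with an estimated correlation (not passed). Of 30 S phase genes 28 were higher (28 adjusted over the list alone; camera adjusted p = 9.59e-17), and this call was kept with an estimated correlation (adjusted p = 0.0451 with an estimated correlation). The replicative helicase gene Mcm5 was at 174 ± 10 and 31.8 ± 6.5 CPM (log2FC 2.45, adjusted p = 1.79e-14). Genes of G2 and M phase were mostly at low levels, with 17 of 30 higher and 2 lower in 41BB+ cells (17 and 2 adjusted over the list alone). For G2 and M phase, camera gave adjusted p = 0.000110, or 0.250 with an estimated correlation. The 2 lower were Cenpa (-1.25), which encodes the centromeric histone, and Kif23 (-0.77), which encodes a kinesin of cytokinesis.

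Members of 5 metabolic lists were mostly higher in 41BB+ cells at 0 h too. Of 34 nuclear-encoded genes of oxidative phosphorylation, 29 were higher in 41BB+ cells (29 adjusted over the list alone). For oxidative phosphorylation, camera gave adjusted p = 1.34e-10, or 0.123 with an estimated correlation. Of 22 genes of the tricarboxylic acid cycle 15 were higher and 2 lower (16 and 2 adjusted over the list alone). For the tricarboxylic acid cycle, camera gave adjusted p = 0.000330, or 0.0954 with an estimated correlation. Of 31 genes of amino acid and one-carbon metabolism 16 were higher (16 higher and 1 lower adjusted over the list alone; camera adjusted p = 9.27e-05, or 0.131 with an estimated correlation). The folate cycle genes Shmt1 (3.35) and Mthfd1 (2.19) and the amino acid transporter gene Slc7a5 (2.16) were among them. Cholesterol synthesis genes were higher in 16 of 22 cases (16 adjusted over the list alone). For cholesterol synthesis, camera gave adjusted p = 3.09e-05, or 0.131 with an estimated correlation. Glycolysis genes were higher in 12 and lower in 3 of 23 cases (13 and 3 adjusted over the list alone; camera adjusted p = 0.00162, or 0.458 with an estimated correlation). The lactate dehydrogenase gene Ldha (chromosome 7, 46841475 to 46855627) was at 652 ± 30 against 174 ± 6.5 CPM (log2FC 1.91).

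Polyamines are small cations made from ornithine and S-adenosylmethionine, and one of them, spermidine, is the substrate for the hypusine residue of the translation factor eIF5A. Of 23 genes of polyamine synthesis, turnover and transport, 12 were higher in 41BB+ cells at 0 h and 11 did not pass (12 higher adjusted over the list alone). Polyamines are the theme of the series, so the count is not independent evidence of its direction. For the list, camera gave adjusted p = 0.00639 (passed), or 0.138 with an estimated correlation (not passed). Odc1 (chromosome 12, 17544794 to 17551505), which encodes ornithine decarboxylase, the first enzyme of the pathway, stood at 279 ± 23 against 78.2 ± 38 CPM (log2FC 1.84, adjusted p = 2.08e-05). The spermidine synthase gene Srm (chromosome 4, 148591503 to 148594993) was at 141 ± 30 against 16.7 ± 5.8 CPM (log2FC 3.07, adjusted p = 2.48e-07) and the spermine synthase gene Sms (chromosome X, 157443855 to 157492287) at 58.8 ± 2.6 against 31.9 ± 4.4 CPM (log2FC 0.89, adjusted p = 5.80e-05). Oaz1, which encodes antizyme, and Azin1, which encodes the antizyme inhibitor, were both higher (log2FC 0.62 and 0.53). Amd1, which encodes S-adenosylmethionine decarboxylase, had a log2FC of 0.32 (adjusted p = 0.205), and its near-identical copy Amd2 was among the 12. The catabolic genes Sat1 (-0.21, adjusted p = 0.50), Smox (-0.26, 0.61) and Paox (0.72, 0.142) did not pass. Eif5a (chromosome 11, 69916714 to 69921958) was at 1052 ± 43 against 168 ± 8.9 CPM (log2FC 2.64, adjusted p = 1.34e-10). Dhps, which encodes the first enzyme of hypusine formation, was higher (log2FC 0.72, adjusted p = 0.0147), a call lost without 41BB+ replicate 2 (adjusted p = 0.111), 41BB+ replicate 3 (0.0703) or 41BB- replicate 1 (0.0855). Dohh, the second enzyme, had too few counts to be tested, so hypusination was not tested as a list.

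Genes of the naive state, of the interferon response and of CD8 T cell identity were lower in 41BB+ cells at 0 h. Of 20 genes of naive and central memory T cells 14 were lower and 1 higher (15 and 1 adjusted over the list alone). For naive genes, camera gave adjusted p = 2.27e-07, or 0.103 with an estimated correlation. The interleukin-7 receptor gene Il7r (chromosome 15, 9505788 to 9530176) was at 46.6 ± 11 against 407 ± 34 CPM (log2FC -3.12, adjusted p = 9.79e-09). S1pr1, whose product lets T cells leave lymphoid tissue, was at 59.9 ± 3.6 against 386 ± 33 CPM (log2FC -2.69, adjusted p = 8.43e-07). The 1 higher member was Id3 (0.92), an inhibitor of E proteins. Of 28 interferon response genes 19 were lower (20 adjusted over the list alone). For the interferon response, camera gave adjusted p = 2.27e-07, or 0.131 with an estimated correlation. Of 12 CD8 identity genes 9 were lower and 1 higher (9 and 1 adjusted over the list alone; camera adjusted p = 0.000500, or 0.0954 with an estimated correlation). The T cell receptor zeta chain gene Cd247 (-0.99) and the transcription factor gene Runx3 (-1.0) were lower, and Zap70 (0.37), a kinase gene of T cell receptor signaling, was higher.

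Other lists did not pass by camera at 0 h. For effector and cytotoxic genes 7 of 22 were higher and 2 lower in 41BB+ cells (7 and 2 adjusted over the list alone; camera adjusted p = 0.290), for coinhibitory receptors 6 and 2 of 17 (6 and 2 alone; 0.0905), for chemokine receptors and homing 2 and 7 of 21 (3 and 7 alone; 0.0554), and for the memory-phenotype list 3 and 3 of 16 (4 and 4 alone; 0.826). Without the filter on low counts the first 3 of these passed (camera adjusted p = 0.0383, 0.00252 and 0.0422), and the coinhibitory list also passed without 41BB- replicate 2 (0.0408). TCR-induced early response genes were higher in 10 and lower in 9 of 29 cases (11 and 9 alone; 0.720), with Myc (1.53) and Irf4 (2.26) higher and Cd69 (-1.13) lower. The counts higher and lower were 8 and 3 of 23 for the TNF superfamily without Tnfrsf9 (8 and 4 alone; 0.768), 4 and 6 of 18 for cytokines and their receptors (4 and 6 alone; 0.444), 5 and 3 of 15 for regulatory T cell genes (6 and 3 alone; 0.512), 2 and 5 of 18 for fatty acid oxidation (2 and 5 alone; 0.350) and 3 and 1 of 33 for cytosolic ribosomal proteins (2 higher alone; 0.826). They were 8 and 9 of 26 for apoptosis regulators (8 and 10 alone; 0.512), 4 and 7 of 20 for NF-kB feedback (6 and 9 alone; 0.526) and 6 and 6 of 17 for heat shock genes (7 and 7 alone; 0.487).

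Markers of other cells were compared at 0 h as well. Of CD4 helper genes 1 was higher and 2 were lower of 9 (1 and 2 adjusted over the list alone; camera adjusted p = 0.826), of NK cell genes 2 and 1 of 4 (camera adjusted p = 0.512), and of B cell genes 1 and 3 of 11 (1 and 3 adjusted over the list alone; 0.714). Of 4 innate-like and gamma-delta T cell genes 2 were lower (camera adjusted p = 0.350), and of 11 dendritic cell genes 2 were lower (1 adjusted over the list alone; 0.512). For the 4 tested myeloid genes edgeR called 0, with 0 at an unadjusted p under 0.05 and 0 by DESeq2 (camera adjusted p = 0.826). The immunoglobulin heavy chain gene Ighm stood at 88.1 ± 4.2 CPM in 41BB+ and 227 ± 12 CPM in 41BB- cells (log2FC -1.37). The sign of the median, the mean and the test did not match for 6 lists. The camera direction was down for all 6, with a median and mean log2 fold change of 0.23 and 0.31 for B cell, 0.06 and 0.09 for CD4 helper, 0.10 and -0.08 for dendritic cell, -0.23 and 0.10 for cytokine, -0.06 and 0.02 for ribosomal protein and -0.08 and 0.04 for NF-kB feedback genes. The plasma cell, erythroid and platelet, and stromal and endothelial lists had fewer than 4 tested members and were not tested.

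**Figure D1:**
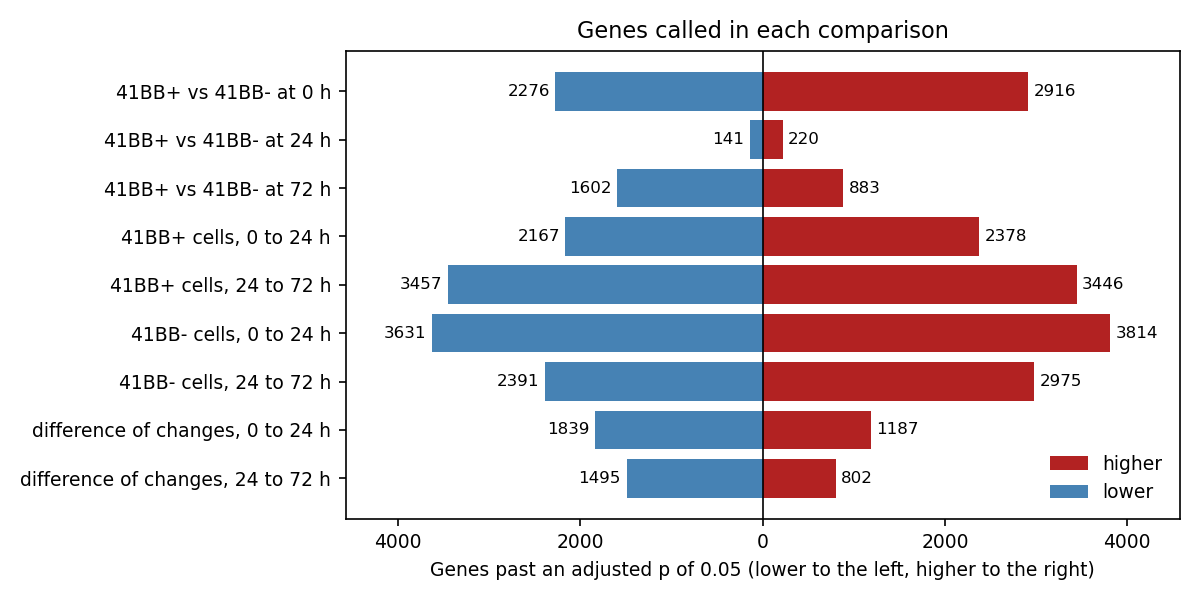
Number of genes past an adjusted p of 0.05 (edgeR) in each comparison, higher to the right and lower to the left. Between populations the bars reach 2916 and 2276 at 0 h, 220 and 141 at 24 h, and 883 and 1602 at 72 h.

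The 24 h comparison was made during activation. Tnfrsf9 stood at 141 ± 9.2 CPM in 41BB+ and 172 ± 9.2 CPM in 41BB- cells and did not pass (log2FC -0.29, adjusted p = 0.621). Cd8a (-0.37, adjusted p = 0.106), Cd8b1 (-0.38, 0.184) and Foxp3 (0.54, 0.849) did not pass either. With only the compared groups in the fit Cd8a and Cd8b1 did (adjusted p = 0.00941 and 0.00893), as with a block within the time (0.0132 and 0.00521), Cd8a with voom (0.0242) and Cd8b1 without the filter (0.0414). Gzmb was higher in 41BB+ cells, at 145 ± 47 against 23.9 ± 8.4 CPM (log2FC 2.6, adjusted p = 0.00281). Arhgap19 (chromosome 19, 41766588 to 41802047), a gene of cytokinesis, stood at 39.6 ± 2.7 against 8.18 ± 2.7 CPM (log2FC 2.27, adjusted p = 4.79e-07). Cdc20 (chromosome 4, 118432901 to 118437352), an activator of the anaphase-promoting complex, stood at 75.6 ± 12 against 17.9 ± 2.4 CPM (log2FC 2.08, adjusted p = 4.79e-07). The scaffold gene Mpp2 (chromosome 11, 102057015 to 102088515) was also higher (15.6 ± 3.7 against 3.71 ± 1.8 CPM, log2FC 2.02, adjusted p = 0.00145). Lower in 41BB+ cells were the chemokine gene Ccl1 (5.08 ± 3.5 against 28.5 ± 4.9 CPM, log2FC -2.47, adjusted p = 0.00286) and Ypel3 (chromosome 7, 126776955 to 126780514, 4.55 ± 3.0 against 16.8 ± 4.5 CPM, log2FC -1.88, adjusted p = 0.00112). In all, 361 genes differed at 24 h, 220 higher and 141 lower in 41BB+ cells, of which 155 by at least 2-fold. The count was 236 without 41BB+ replicate 2, 197 (142 higher and 55 lower) without 41BB+ replicate 3, 226 without 41BB- replicate 1, 181 without 41BB- replicate 2 and 215 (102 higher and 113 lower) without 41BB- replicate 3, so the excess of higher genes was not kept in each case. It rose to 577 with the replicate number as a block within each time and to 550 with voom and library quality weights.

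Another 4 genes among the largest differences at 24 h lost the call when libraries were left out, while their folds stayed large (log2FC 2.35 to 2.85 for Tead1, -3.22 to -2.43 for Pgpep1l, -2.95 to -1.78 for Slc6a19 and -2.3 to -1.62 for Ifit1bl1). Tead1 (chromosome 7, 112679318 to 112906807, 20.2 ± 3.6 against 3.44 ± 1.3 CPM, log2FC 2.56, adjusted p = 0.0415), a transcription factor gene of the Hippo pathway, was lost when any 1 of the 6 libraries was left out (adjusted p = 0.0940, 0.0861 and 0.160 without 41BB+ replicates 1 to 3, and 0.101, 0.170 and 0.186 without 41BB- replicates 1 to 3) and with the Y-linked covariate (0.0519). The peptidase gene Pgpep1l (chromosome 7, 68236610 to 68264233, 1.57 ± 0.93 against 11.4 ± 1.9 CPM, log2FC -2.85, adjusted p = 0.0368) was lost likewise (0.0828, 0.130, 0.177, 0.118, 0.10 and 0.0699 in the same order) and with voom (0.134). The amino acid transporter gene Slc6a19 (log2FC -2.34, adjusted p = 0.0388) was lost without 41BB+ replicates 2 (0.119) or 3 (0.103), without 41BB- replicates 1 (0.112), 2 (0.138) or 3 (0.0824), and with voom (0.145). The interferon-induced gene Ifit1bl1 (log2FC -1.91, adjusted p = 0.0363) was lost without 41BB+ replicates 1 (0.122) or 3 (0.182) and without 41BB- replicates 1 (0.0688), 2 (0.111) or 3 (0.120).

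Genes of G2 and M phase were higher in 41BB+ cells at 24 h in 23 of 30 cases (30 adjusted over the list alone; camera adjusted p = 8.01e-28), and this call was kept with an estimated correlation (adjusted p = 0.0123 with an estimated correlation). The ubiquitin-conjugating enzyme gene Ube2c was at 94.2 ± 22 against 27.5 ± 4.1 CPM and Cenpa at 50.1 ± 6.2 against 14 ± 4.8 CPM (log2FC 1.78 and 1.85). S phase genes passed with 1 higher, Rrm2 (0.65), and 1 lower of 30 (2 and 1 adjusted over the list alone), and not without 41BB+ replicate 1 (0.0552). For S phase, camera gave adjusted p = 0.00621, or 0.558 with an estimated correlation. Naive and central memory genes were lower in 4 of 20 cases (8 adjusted over the list alone), with Il7r at 38.7 ± 14 against 135 ± 20 CPM (log2FC -1.8, adjusted p = 0.000356). For naive genes, camera gave adjusted p = 1.07e-07, or 0.198 with an estimated correlation. Interferon response genes were lower in 3 of 28 cases (7 adjusted over the list alone). For the interferon response, camera gave adjusted p = 1.28e-05, or 0.461 with an estimated correlation. The integrin gene Itgae was at 29.2 ± 3.0 against 58.2 ± 7.9 CPM (log2FC -1.0, adjusted p = 0.00116). The transcription factor gene Ikzf2, at 94.9 ± 2.4 against 38.9 ± 13 CPM, was higher (log2FC 1.29, adjusted p = 0.00106), and the inhibitory receptor gene Vsir was lower (log2FC -1.15, adjusted p = 2.85e-06).

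At 24 h 3 metabolic lists passed, with few members, and 3 did not. By edgeR none passed of 34 oxidative phosphorylation genes (0, with 1 higher and 1 lower at an unadjusted p under 0.05, and 0 by DESeq2; camera adjusted p = 0.325), of 22 cholesterol synthesis genes (0, with 1 higher, and 0; 0.213) and of 18 fatty acid oxidation genes (0, with 1 and 1, and 0; 0.927). Glycolysis had 1 higher of 23, Eno1 (558 ± 39 against 369.6 ± 5.2 CPM), which encodes enolase (1 adjusted over the list alone). For glycolysis, camera gave adjusted p = 0.00480, or 0.564 with an estimated correlation. Amino acid and one-carbon metabolism had 1 higher of 31 (1 adjusted over the list alone; camera adjusted p = 0.0225, or 0.558 with an estimated correlation), and the call was lost without 41BB+ replicate 1 (0.0552). The tricarboxylic acid cycle had 2 higher of 22 (2 adjusted over the list alone; camera adjusted p = 0.0343, or 0.461 with an estimated correlation), lost without 41BB+ replicate 1 (0.0649), 41BB+ replicate 3 (0.0533) or 41BB- replicate 2 (0.139) and with a block within the time (0.0739). TCR-induced early response genes had 1 lower of 29 (2 adjusted over the list alone), the feedback inhibitor gene Spry1 (22.9 ± 5.0 against 64 ± 6.9 CPM). For the early response, camera gave adjusted p = 0.0343, or 0.567 with an estimated correlation. That call was lost without 41BB+ replicates 1 (0.0649) or 2 (0.0757), without 41BB- replicates 1 (0.0582) or 2 (0.0889), and with a block across times (0.0527) or within the time (0.0739). Homing genes had 3 lower of 21 (2 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.0371, or 0.558 with an estimated correlation), lost without 41BB+ replicate 3 (0.353) or 41BB- replicate 1 (0.125) and with a block across times (0.0517) or within the time (0.0694).

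No gene of the polyamine list passed between populations at 24 h by edgeR (0 of 23, with 1 higher and 1 lower at an unadjusted p under 0.05, and 0 by DESeq2), nor did the list (camera adjusted p = 0.262; not independent evidence, since polyamines are the theme of the series). Odc1 was at 622 ± 8.5 CPM in 41BB+ and 507 ± 18 CPM in 41BB- cells (log2FC 0.29, adjusted p = 0.714), Srm at 258 ± 13 and 224 ± 15 CPM (0.2, 0.849) and Eif5a at 1184 ± 51 and 1081 ± 102 CPM (0.13, 0.855). Amd1 (0.13), Sms (-0.03), Sat1 (0.24), Smox (-1.0), Paox (0.31), Oaz1 (-0.12), Azin1 (0.13) and Dhps (0.03) did not pass either. Ribosome biogenesis genes, all higher at 0 h, had 0 of 28 past the threshold at 24 h by edgeR, with 1 higher at an unadjusted p under 0.05 and 1 by DESeq2 (camera adjusted p = 0.156).

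The 72 h comparison was made late in the culture. Tnfrsf9 was lower in 41BB+ cells (22.5 ± 12 against 54.5 ± 9.2 CPM, log2FC -1.28, adjusted p = 0.000354). Cd8a was at 440.1 ± 47 and 394 ± 58 CPM (0.16, adjusted p = 0.389) and Cd8b1 at 856 ± 163 and 643 ± 136 CPM (0.41, 0.0351), the last lost with only the compared groups in the fit (0.0729) and without 41BB+ replicates 1 (0.104) or 2 (0.0593) or 41BB- replicate 3 (0.121). Foxp3 was at 19.2 ± 8.2 and 5.34 ± 2.5 CPM (1.84, 0.0178), lost without 41BB+ replicate 2 (0.102) or 41BB- replicates 2 (0.0694) or 3 (0.0613). The largest differences were genes lower in 41BB+ cells. Bnip3 (chromosome 7, 138890836 to 138909519), a mitophagy gene, was at 4.45 ± 1.1 against 79.2 ± 57 CPM (log2FC -4.15, adjusted p = 3.03e-06). The adenylate kinase gene Ak4 (chromosome 4, 101419277 to 101466995) was at 0.506 ± 0.64 against 17.8 ± 13 CPM (log2FC -5.07, adjusted p = 6.18e-05), and the lactate exporter gene Slc16a3 (chromosome 11, 120948480 to 120960868) was at 4.61 ± 3.3 against 72.7 ± 48 CPM (log2FC -3.97, adjusted p = 0.000261). The angiogenic factor gene Vegfa (chromosome 17, 46016993 to 46032369, log2FC -2.95, adjusted p = 0.000386) and the transcription factor gene Bhlhe40 (log2FC -2.92, adjusted p = 0.00391, lost with voom at 0.0630) were lower too. These 5 genes varied widely among 41BB- libraries. Bnip3 was at 28.9, 66.9 and 142 CPM in 41BB- replicates 1 to 3.

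Higher in 41BB+ cells at 72 h were the protease gene Prss12 (chromosome 3, 123446913 to 123506597, log2FC 2.59, adjusted p = 0.00216), the channel genes Kcnh5 (chromosome 12, 74897220 to 75177332, log2FC 2.54, adjusted p = 0.00754, with log2FC from 2.07 to 3.75 when 1 library was left out) and Cnga1 (chromosome 5, 72603696 to 72644275, log2FC 2.31, adjusted p = 0.000807) and the interferon-inducible Ifi213 (chromosome 1, 173566283 to 173599274, 44.4 ± 26 against 8.5 ± 4.1 CPM, log2FC 2.37, adjusted p = 0.00762). The NK receptor gene Klrd1 was also higher (136 ± 76 against 31.4 ± 8.5 CPM, log2FC 2.11, adjusted p = 0.000104), as was Ikzf2 (571 ± 97 against 212 ± 25 CPM, log2FC 1.43, adjusted p = 1.80e-05). In all, 2485 genes differed at 72 h, 883 higher and 1602 lower in 41BB+ cells, and 662 of them by at least 2-fold.

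Genes of ribosome biogenesis were lower in 41BB+ cells at 72 h in 26 of 28 cases, with 1 higher, Wdr12 (0.9), which encodes a ribosome assembly factor (26 and 1 adjusted over the list alone). For ribosome biogenesis, camera gave adjusted p = 3.21e-16, or 0.0834 with an estimated correlation. Ncl was at 946 ± 17 against 1824 ± 161 CPM (log2FC -0.95). Of 30 S phase genes 29 were lower (30 adjusted over the list alone), with Mcm2 at 116 ± 13 against 238 ± 5.7 CPM (log2FC -1.03, adjusted p = 2.63e-07). For S phase, camera gave adjusted p = 3.37e-15, or 0.0673 with an estimated correlation. Of 30 genes of G2 and M phase 9 were lower and 1 higher (12 and 1 adjusted over the list alone; camera adjusted p = 0.0616), and the list passed with a block within the time (0.0110).

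Glycolysis genes were lower in 41BB+ cells at 72 h in 17 of 23 cases (18 adjusted over the list alone; camera adjusted p = 8.26e-16, or 0.0834 with an estimated correlation). Ldha was at 433 ± 64 against 1344 ± 248 CPM (log2FC -1.63, adjusted p = 9.21e-10) and the triosephosphate isomerase gene Tpi1 at 54.7 ± 15 against 309 ± 90 CPM (log2FC -2.5, adjusted p = 2.55e-09). Of 34 genes of oxidative phosphorylation 13 were lower (15 adjusted over the list alone). For this list, camera gave adjusted p = 1.57e-06, or 0.208 with an estimated correlation. The mitochondrial share (10.9% in 41BB+, 9.14% in 41BB-) was mostly ribosomal RNA (9.97% and 8.21%). Of 22 genes of the tricarboxylic acid cycle 11 were lower (12 adjusted over the list alone; camera adjusted p = 0.000224, or 0.0834 with an estimated correlation). Of 22 cholesterol synthesis genes 10 were lower (12 adjusted over the list alone; camera adjusted p = 8.43e-07, or 0.0834 with an estimated correlation). Of 31 genes of amino acid and one-carbon metabolism 15 were lower (18 adjusted over the list alone). For amino acid metabolism, camera gave adjusted p = 2.89e-06, or 0.0834 with an estimated correlation.

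Of 20 naive and central memory genes 14 were higher in 41BB+ cells at 72 h and 1, Igfbp4 (-1.77), was lower (15 and 1 adjusted over the list alone). For naive genes, camera gave adjusted p = 2.18e-07, or 0.0834 with an estimated correlation. Il7r was at 363 ± 82 against 158 ± 16 CPM (log2FC 1.2, adjusted p = 0.000814) and S1pr1 at 220.3 ± 64 against 97.5 ± 15 CPM (log2FC 1.17, adjusted p = 0.00489). Interferon response genes were higher in 6 of 28 cases (8 adjusted over the list alone; camera adjusted p = 0.000579, or 0.324 with an estimated correlation), and the list call was lost without 41BB+ replicate 3 (0.0524). NF-kB feedback genes were higher in 8 of 20 cases and lower in 1, Cd83 (8 and 1 adjusted over the list alone). For NF-kB feedback, camera gave adjusted p = 0.000585, or 0.121 with an estimated correlation. The Cd83 call (log2FC -1.11, adjusted p = 0.00466) was lost with only the compared groups in the fit (0.0766) and with voom (0.125). Of 12 CD8 identity genes 4 were higher (4 adjusted over the list alone). For CD8 identity, camera gave adjusted p = 0.00601, or 0.10 with an estimated correlation.

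In the polyamine list 8 of 23 genes were lower in 41BB+ cells at 72 h and 1 was higher (11 and 1 adjusted over the list alone; not independent evidence of its direction, as at the other times). For the list, camera gave adjusted p = 0.00719 (passed), or 0.158 with an estimated correlation (not passed). Srm was at 13.8 ± 7.5 against 36.9 ± 8.8 CPM (log2FC -1.42, adjusted p = 0.00446), the methylthioadenosine phosphorylase gene Mtap at 21.6 ± 4.5 against 46 ± 8.2 CPM (log2FC -1.09, adjusted p = 2.34e-05) and the arginine transporter gene Slc7a1 at 52.2 ± 12 against 101 ± 15 CPM (log2FC -0.95, adjusted p = 5.49e-05). Sat1 (chromosome X, 155213132 to 155216449), which encodes the spermidine and spermine acetyltransferase of polyamine breakdown, was the higher one (68.8 ± 16 against 34.5 ± 6.4 CPM, log2FC 1.0, adjusted p = 0.00146). Smox, which encodes spermine oxidase, was lower (log2FC -1.11, adjusted p = 0.024), a call lost without the filter (0.0973), with only the compared groups (0.0723), with voom (0.0791) and without 41BB+ replicates 1 (0.0820) or 2 (0.111) or 41BB- replicate 3 (0.195). Azin1 was lower (log2FC -0.48, adjusted p = 0.00791), lost with only the compared groups (0.0828) and without 41BB+ replicates 1 (0.0504) or 2 (0.0749) or 41BB- replicates 1 (0.101) or 3 (0.0799). Odc1 stood at 71.1 ± 20 against 112 ± 14 CPM and did not pass (-0.65, 0.088), but did without the filter (0.0116), with the replicate block across times (0.0321) and with the block within the time (0.00383). Amd1 (-0.49, 0.104) passed with the block within the time (0.0284) and without 41BB+ replicate 1 (0.0274). Sms (0.03), Paox (-0.3), Oaz1 (-0.2) and Dhps (0.04) did not pass. Eif5a was at 273 ± 92 against 619.9 ± 74 CPM (log2FC -1.18, adjusted p = 3.85e-05).

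**Figure D2:**
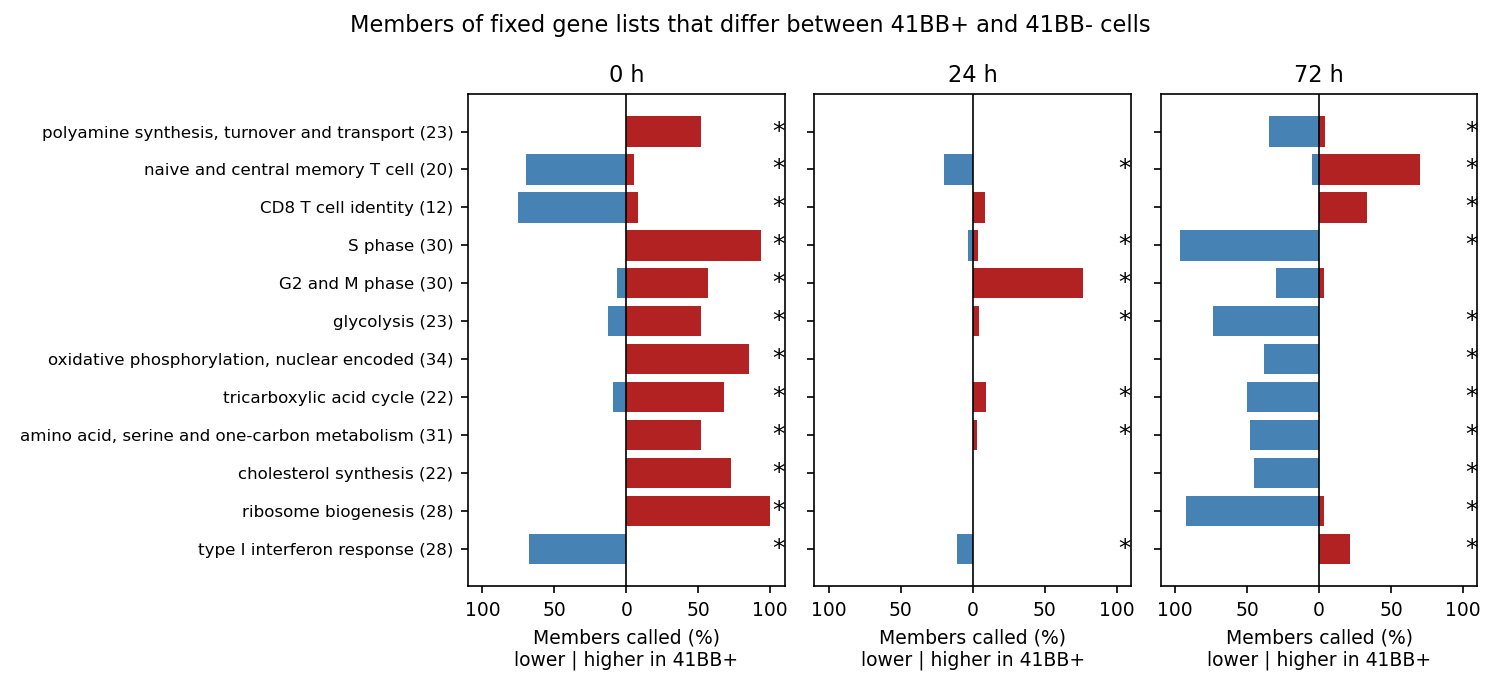
Percentage of the tested members of 12 gene lists that were higher (right) or lower (left) in 41BB+ than in 41BB- cells at 0, 24 and 72 h, with an asterisk where the camera adjusted p was under 0.05. Ribosome biogenesis has 28 of 28 genes higher at 0 h and 26 of 28 lower at 72 h.

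Many genes that differed at 0 h differed in the opposite direction at 72 h. Of the genes called at both times, 1237 were higher at 0 h and lower at 72 h (355 expected for independent lists among 13150 genes) and 614 were lower and then higher (153 expected), against 28 higher at both (196 expected) and 31 lower at both (277 expected). Il7r, S1pr1 and Cd247 were lower at 0 h and higher at 72 h, and Ncl, Mcm5, Ldha, Mthfd1, Srm and Eif5a were higher at 0 h and lower at 72 h. Between 0 h and 24 h, 93 genes were higher at both times (48.8 expected), 118 lower at both (24.4), 6 higher and then lower (31.3) and 24 lower and then higher (38.1). Between 24 h and 72 h, 91 were higher and then lower (26.8 expected), 96 lower and then higher (9.47), 9 higher at both (14.8) and 4 lower at both (17.2). Genes are not independent, so the expected numbers are a guide only. With the block within each time, the genes called in the same direction numbered 349 for 0 h and 24 h, against 211 without it, and 27 for 24 h and 72 h, against 13, and 101 for 0 h and 72 h, against 59. DESeq2 gave 23 for 24 h and 72 h.

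The comparisons over time asked how each population changed in culture, but animals also differed between times. Replicate 3 held 750 to 945 Y-linked counts at 0 h and 24 h. At 72 h it held 0 in 41BB+ and 5 in 41BB- cells, so time and sex were partly confounded. From 0 h to 24 h, 4545 genes changed in 41BB+ cells, 2378 up and 2167 down. Tnfrsf9 fell from 383 ± 33 to 141 ± 9.2 CPM (log2FC -1.44, adjusted p = 3.58e-06), Cd8b1 fell (log2FC -0.76, adjusted p = 0.000112) and Foxp3 did not pass (-0.02, 0.983). Cd8a fell (log2FC -0.44, adjusted p = 0.00481), a call lost without 0 h replicate 2 (0.118) and without 24 h replicates 2 (0.0505) or 3 (0.0656). The cytokine-induced inhibitor gene Socs2 rose at least 73.0-fold from 0 counts, and the mitotic genes Ube2c (6.26) and Hmmr (6.25), the cytokine gene Il2 (0.458 ± 0.15 to 33.9 ± 26 CPM, log2FC 6.1, adjusted p = 1.80e-05) and the interferon-inducible Ifi211 (6.04) rose most. The interferon-induced family gene Ifitm10 fell to 1 count (ratio 158, 95% counting interval 28.0 to 6300) and Arhgap20 to 3 counts (ratio 47.4, 15.9 to 233), and Eomes fell from 558 ± 40 to 20.1 ± 11 CPM (log2FC -4.8, adjusted p = 1.56e-09), the integrin gene Itgax (-5.34) and the potassium channel gene Kcnc1 (-4.7) with it.

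Proliferation genes rose in 41BB+ cells from 0 h to 24 h. Genes of G2 and M phase rose in 29 and fell in 1 of 30 cases (29 and 1 adjusted over the list alone). For G2 and M phase, camera gave adjusted p = 4.71e-31, or 0.00539 with an estimated correlation. S phase genes rose in 29 of 30 (29 adjusted over the list alone). For S phase, camera gave adjusted p = 6.36e-24, or 0.00539 with an estimated correlation. CD8 identity genes fell in 11 of 12 cases (11 adjusted over the list alone; camera adjusted p = 1.79e-05, or 0.0242 with an estimated correlation), and Runx3 rose (0.95). In all, 15 lists passed, 9 up and 6 down, and 3 of them with an estimated correlation. Among these, NK cell genes fell in 4 of 4 cases (4 adjusted over the list alone; camera adjusted p = 0.0317, or 0.278 with an estimated correlation), lost without 0 h replicate 3 (0.0844) or 24 h replicates 1 (0.0670) or 3 (0.0660). By camera the B cell (adjusted p = 0.10), dendritic (0.138) and myeloid (0.374) lists passed only without 24 h replicate 2 (0.0090, 0.0421 and 0.0314).

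Of the polyamine genes 12 rose and 2 fell of 23 in 41BB+ cells from 0 h to 24 h (13 and 3 adjusted over the list alone; not independent evidence of direction). The list passed by camera (adjusted p = 0.0317, or 0.279 with an estimated correlation), and not without 0 h replicate 1 (0.0716). Odc1 rose from 279 ± 23 to 622 ± 8.5 CPM (log2FC 1.16, adjusted p = 0.00118), Srm from 141 ± 30 to 258 ± 13 CPM (log2FC 0.87, adjusted p = 0.0106), and Amd1 (0.95), Sms (0.5) and Azin1 (0.86) rose. Paox, which encodes a polyamine oxidase, rose (log2FC 1.02, adjusted p = 0.0219), lost without 0 h replicate 1 (0.0556). Oaz1 fell (log2FC -0.38, adjusted p = 0.0199), lost without the filter (0.126) and without 0 h replicates 1 (0.0508), 2 (0.149) or 3 (0.0871) or 24 h replicates 1 (0.141) or 2 (0.127). Smox (-0.91, 0.0501) passed only without 0 h replicate 3 (0.0261). Sat1 (-0.15, 0.632), Dhps (0.11, 0.74) and Eif5a (0.17, 0.444) did not pass.

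From 0 h to 24 h, 7445 genes changed in 41BB- cells, 3814 up and 3631 down. Tnfrsf9 rose from 6.68 ± 1.8 to 172 ± 9.2 CPM (log2FC 4.68, adjusted p = 1.46e-12). Cd8b1 fell from 869.5 ± 101 to 301 ± 8.0 CPM (log2FC -1.53, adjusted p = 6.55e-10), and Cd8a fell (log2FC -0.41, adjusted p = 0.0040), lost without 0 h replicate 3 (0.0585). Foxp3 (1.83, 0.0707) passed with voom (0.0443), without 0 h replicate 1 (log2FC 5.84, adjusted p = 0.00236) and without 24 h replicate 3 (0.0443). Several genes rose from 0 counts: Mcm10 at least 415-fold, the chemokine gene Ccl3 at least 346-fold, Il2 at least 182-fold, the mitotic kinesin gene Kif18b at least 64.8-fold and the AP-1 gene Fosl1 at least 60-fold. The glutathione breakdown gene Ggt1 fell to 3 counts (ratio 188, 95% counting interval 64.0 to 916), the interferon-induced Mx1 to 3 counts (ratio 71.3, 24.0 to 349), and Baiap3 (-5.4), Fos (-5.31) and the quiescence gene family member Slfn5 (-5.13) fell too.

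Growth and replication lists rose in 41BB- cells from 0 h to 24 h. S phase genes rose in 30 of 30 cases (30 adjusted over the list alone; camera adjusted p = 1.65e-20, or 0.0193 with an estimated correlation) and genes of G2 and M phase rose in 28 and fell in 1 of 30 (28 and 1 adjusted over the list alone; camera adjusted p = 6.57e-15, or 0.0448 with an estimated correlation). Ribosome biogenesis rose in 28 of 28 (28 adjusted over the list alone; camera adjusted p = 4.93e-14, or 0.103 with an estimated correlation). Effector genes rose in 8 and fell in 11 of 22, with a median log2FC of -0.49, a mean of 0.51 and a camera direction of down (adjusted p = 0.996). In all, 15 lists passed, 9 up and 6 down, and 3 of them with an estimated correlation. Among the lists of other cells, B cell genes fell in 4 of 11 cases (4 adjusted over the list alone; camera adjusted p = 0.0255, or 0.285 with an estimated correlation), and dendritic cell genes fell in 6 of 11 without passing as a list (1 up and 7 down adjusted over the list alone; 0.11).

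Of the polyamine genes 15 rose and 2 fell of 23 in 41BB- cells from 0 h to 24 h (16 and 2 adjusted over the list alone; camera adjusted p = 0.00289, or 0.125 with an estimated correlation; not independent evidence of direction). Odc1 rose from 78.2 ± 38 to 507 ± 18 CPM (log2FC 2.7, adjusted p = 1.60e-07), Srm from 16.7 ± 5.8 to 224 ± 15 CPM (log2FC 3.75, adjusted p = 8.77e-09) and Eif5a from 168 ± 8.9 to 1081 ± 102 CPM (log2FC 2.68, adjusted p = 3.34e-11). Amd1 (1.14), Sms (1.42), Paox (1.43), Azin1 (1.26) and Dhps (0.8) rose. Sat1 fell (log2FC -0.6, adjusted p = 0.0223), lost without 0 h replicates 2 (0.0932) or 3 (0.0892) or 24 h replicates 2 (0.115) or 3 (0.0952). Oaz1 rose (log2FC 0.35, adjusted p = 0.0213), lost without 0 h replicate 1 (0.0713) or 24 h replicate 3 (0.0580). Smox had a log2FC of -0.17 (adjusted p = 0.691).

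In 41BB+ cells 6903 genes changed from 24 h to 72 h, 3446 up and 3457 down. Tnfrsf9 fell from 141 ± 9.2 to 22.5 ± 12 CPM (log2FC -2.65, adjusted p = 1.23e-09), while Cd8b1 (log2FC 1.89, adjusted p = 1.91e-11) and Foxp3 (log2FC 2.75, adjusted p = 0.000233) rose. Cd8a did not pass (0.26, 0.0672), but did with only the compared groups (0.0415), the Y-linked covariate (0.0357), voom (0.0432), and without 24 h replicate 1 (0.0390) or 72 h replicate 3 (0.0279). The integrin gene Itgb3 (chromosome 11, 104608000 to 104670476) rose from 0.923 ± 0.58 to 109 ± 5.8 CPM (log2FC 6.85, adjusted p = 1.12e-15). The calcium channel subunit gene Cacnb3 rose from 2 counts (ratio 137, 95% counting interval 37.4 to 1130), the guanylate cyclase gene Gucy2e from 2 counts (ratio 132, 36.2 to 1100), the integrin gene Itga2 from 1 count (ratio 118, 20.7 to 4690), and S100a6 (log2FC 6.31, adjusted p = 1.34e-09). The nucleoside transporter gene Slc29a2 (at least 46.2-fold lower) and the Notch regulator gene Dtx1 (at least 34.0-fold lower) fell to 0 counts, and Ccl3 (-6.59), Il2 (-6.0) and Ccl4 (-5.9) fell.

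Of 28 ribosome biogenesis genes 27 fell in 41BB+ cells from 24 h to 72 h and Wdr12 rose (27 and 1 adjusted over the list alone). For ribosome biogenesis, camera gave adjusted p = 2.51e-18, or 0.116 with an estimated correlation. Of 29 TCR-induced early response genes 23 fell and 1 rose (24 and 1 adjusted over the list alone). For the early response, camera gave adjusted p = 9.54e-09, or 0.116 with an estimated correlation. CD8 identity genes rose in 10 of 12 cases (11 adjusted over the list alone; camera adjusted p = 3.67e-06, or 0.0429 with an estimated correlation). In all, 12 lists passed, 3 up and 9 down, and 1 of them with an estimated correlation. Of the polyamine genes 14 fell and 4 rose of 23 (14 and 4 adjusted over the list alone; camera adjusted p = 0.00124, or 0.116 with an estimated correlation; not independent evidence of direction). Odc1 (log2FC -3.13, adjusted p = 3.69e-08), Srm (log2FC -4.23, adjusted p = 2.82e-09), Amd1 (-2.17), Sms (-0.79), Azin1 (-1.33), Dhps (-1.0) and Eif5a (-2.12) fell, and Sat1 rose (log2FC 0.88, adjusted p = 0.0011). Smox (0.3) and Paox (-0.49) did not pass, nor did Oaz1 (0.21, 0.167) except with the Y-linked covariate (0.0476).

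In 41BB- cells 5366 genes changed from 24 h to 72 h, 2975 up and 2391 down. Tnfrsf9 fell from 172 ± 9.2 to 54.5 ± 9.2 CPM (log2FC -1.66, adjusted p = 8.22e-07), and Cd8b1 rose (log2FC 1.09, adjusted p = 5.10e-07). Cd8a (-0.27, 0.0678) passed without the filter (0.00850), without mitochondrial and ribosomal genes (0.0196), with only the compared groups (0.0398) and without 24 h replicate 3 (0.0366) or 72 h replicate 1 (0.00881). Foxp3 (1.46, 0.0633) passed with the replicate block (0.0489), only the compared groups (0.0429) and DESeq2 (0.0421). Gucy2e rose from 1 count (ratio 317, 95% counting interval 56.4 to 12500), Prdm1, which encodes the effector differentiation factor Blimp-1, from 1 count (ratio 293, 52.2 to 11600). The homing receptor gene Gpr15 rose from 3 counts (ratio 174, 59.2 to 846), Fut4 from 1 count (ratio 158, 27.9 to 6270) and the histone gene Hist3h2ba from 1 count (ratio 147, 26.0 to 5860). Npas4 fell to 0 counts (at least 39.9-fold lower), and Il2 (-7.11), Ccl3 (-6.82), Ccl4 (-6.2) and Xcl1 (-4.73) fell. Gzmb rose from 23.9 ± 8.4 to 629 ± 122 CPM (log2FC 4.72, adjusted p = 5.92e-07) and Bnip3 from 4.21 ± 1.1 to 79.2 ± 57 CPM (log2FC 4.24, adjusted p = 2.85e-07).

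Ribosome biogenesis genes fell in 41BB- cells from 24 h to 72 h in 27 of 28 cases (27 adjusted over the list alone; camera adjusted p = 1.02e-20, or 0.0542 with an estimated correlation). Genes of G2 and M phase rose in 30 of 30 (30 adjusted over the list alone). For G2 and M phase, camera gave adjusted p = 2.53e-12, or 0.0542 with an estimated correlation. In all, 11 lists passed, 5 up and 6 down, and none with an estimated correlation. Of the polyamine genes 11 fell and 2 rose of 23 (12 and 3 adjusted over the list alone; camera adjusted p = 0.00186, or 0.137 with an estimated correlation; not independent evidence of direction). Odc1 (log2FC -2.19, adjusted p = 2.83e-06), Srm (log2FC -2.61, adjusted p = 6.26e-07), Amd1 (-1.54), Sms (-0.85), Azin1 (-0.72), Dhps (-1.0) and Eif5a (-0.8) fell. Sat1 (0.12), Smox (0.42) and Paox (0.12) did not pass, nor did Oaz1 (0.29, 0.0683) except with the Y-linked covariate (0.0122), with voom (0.0339) and without 72 h replicate 3 (0.0416).

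The interaction of population and time asked which genes changed differently in the 2 populations. The change from 0 h to 24 h differed for 3026 genes, 1187 with a higher and 1839 with a lower log2 change in 41BB+ cells. For Srm the difference was -2.87 (adjusted p = 2.82e-05), for Odc1 -1.54 (0.00326) and for Eif5a -2.51 (9.49e-08). The change from 24 h to 72 h differed for 2297 genes, 802 with a higher and 1495 with a lower change, with Srm at -1.62 (0.00881) and Eif5a at -1.31 (0.00041). Odc1 (-0.95, 0.0713) did not pass there, but did with the replicate block across times (0.0249) or within the time (0.0021), without the filter (0.0068), with only the compared groups (0.00573) and with voom (0.0355). Amd1 (-0.63, 0.127) passed with the block within the time (0.0391) and without 41BB+ 72 h replicate 1 (0.0360), and Sat1 (0.76, 0.0948) with that block (0.0262), without the filter (0.0420) and without 41BB+ 24 h replicate 2 (0.0434) or 41BB+ 72 h replicate 3 (0.0240). Of the 31 lists tested, 12 differed in the first interval and 14 in the second.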

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

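The tests of scaling, of splits by pairs, of handling genes, of ribosomal RNA reads and of library depth, and the block within each time and the Y-linked covariate, were chosen only after the results were seen. All differences given here were set apart because the change over time differed between the populations by edgeR's test of the interaction, with positive values where the log2 change was higher in 41BB+ cells. From 0 h to 24 h this held for 3026 genes. Of the 60 splits of the libraries 5 gave as many genes. The highest other (4264 genes) exchanged the population labels at 1 time. The other 3 (3059 to 3632) kept the 0 h populations whole. From 24 h to 72 h it held for 2297 genes. Of 60 splits 1 gave as many, the real one, against 1560 in the highest other. Splits relabel populations within times, so they test for no population difference at either time and cannot exclude chance for a differing change. Of the 32 splits that part all pairs of an experiment number, 7 gave as many genes in the first interval, and 1 in the second, the real one, against 1129 in the highest other.

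From 0 h to 24 h the changes differed by -6.12 for Tnfrsf9, 0.77 for Cd8b1, -6.8 for Xcl1, -6.5 for Rgs16 and 3.97 for Maff. Mcm10 (-8.39), Ccl3 (-8.32), Fosl1 (-8.2), Socs2 (6.12) and Ggt1 (4.89) had 0 to 3 counts in a group, so their fitted values depend on the prior count and are no bounds. The Socs2 call was lost without 41BB- 0 h replicate 2 (adjusted p = 0.0826). L1cam (3.65), which encodes an adhesion molecule, was lost with voom (0.174) and without 41BB+ 24 h replicate 2 (0.190). Fos (4.12) was lost without the filter (0.125), with only the compared groups (0.0813), with voom (0.295), and without 41BB+ 0 h replicates 1 (0.0851), 2 (0.0561) or 3 (0.0929), 41BB- 0 h replicates 1 (0.0874) or 2 (0.0888), 41BB+ 24 h replicate 2 (0.420) or 41BB- 24 h replicates 1 (0.0827), 2 (0.0716) or 3 (0.107). Among polyamine genes the differences were -1.54 for Odc1, -2.87 for Srm, -0.92 for Sms and -0.73 for Oaz1, and Eif5a had -2.51.

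From 24 h to 72 h the differences were 0.53 for Cd8a, 0.8 for Cd8b1, 4.45 for Pgpep1l, 4.36 for Ifi213, 4.24 for Emc9, 4.01 for Nacc2, 4.0 for Tmem140, -5.0 for Ak4, -4.72 for Acsl6, -1.62 for Srm and -1.31 for Eif5a. Slc29a2 (-5.14, lost with voom at 0.108), Hist3h2ba (-4.76) and Prdm1 (-4.18) had 0 to 3 counts in a group and are no bounds either, and Prdm1 was lost with voom (0.0761) and without 41BB+ 24 h replicate 1 (0.0738) or 41BB- 24 h replicates 1 (0.0530) or 2 (0.0696). Tnfrsf9 (-0.99) was lost with only the compared groups (0.0632) and without 41BB+ 24 h replicates 1 (0.0613) or 3 (0.0831), 41BB- 24 h replicates 1 (0.0771), 2 (0.0674) or 3 (0.0572), 41BB+ 72 h replicates 1 (0.0957) or 3 (0.0756) or 41BB- 72 h replicates 2 (0.0620) or 3 (0.0929). Azin1 (-0.62) was lost without the filter (0.0969) and without 41BB+ 24 h replicate 3 (0.0827), 41BB- 24 h replicates 1 (0.112) or 3 (0.0511), 41BB+ 72 h replicate 2 (0.0661) or 41BB- 72 h replicates 1 (0.0867) or 3 (0.0754).

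Of the lists, 12 differed in their change from 0 h to 24 h (camera adjusted p, then the adjusted p with an estimated correlation). They rose less or fell more in 41BB+ cells for ribosome biogenesis (1.24e-20, 0.0915), S phase (4.91e-17, 0.0423), oxidative phosphorylation (5.08e-10, 0.169), cholesterol synthesis (0.000239, 0.235), amino acid metabolism (0.00114, 0.236), the tricarboxylic acid cycle (0.00819, 0.206), coinhibitory receptors (0.0114, 0.0915), glycolysis (0.0167, 0.723) and polyamines (0.0254, 0.267, not independent evidence), the last lost without 41BB+ 0 h replicate 2 (0.0527) or 41BB- 0 h replicate 3 (0.0650). They fell less for naive genes (0.000873, 0.267), the interferon response (0.00195, 0.416) and CD8 identity (0.00762, 0.169). From 24 h to 72 h 14 lists differed. They were lower in 41BB+ cells for glycolysis (7.06e-14, 0.0773), S phase (3.27e-13, 0.0773), ribosome biogenesis (3.80e-13, 0.104), G2 and M phase (2.78e-11, 0.0773), amino acid metabolism (2.04e-06, 0.0773), cholesterol synthesis (8.38e-06, 0.104), oxidative phosphorylation (5.10e-05, 0.295), the tricarboxylic acid cycle (0.000152, 0.0773) and polyamines (0.0108, 0.160), and higher for naive genes (3.95e-10, 0.0773), the interferon response (2.04e-06, 0.134), NF-kB feedback (0.000453, 0.104) and CD8 identity (0.00439, 0.103). Homing genes (0.0482, 0.479) lost the call with RLE (0.0543), either block (0.0574 across and 0.0568 within times) or the Y-linked covariate (0.0510), and without 41BB+ 24 h replicate 3 (0.131), 41BB- 24 h replicates 1 (0.111), 2 (0.0506) or 3 (0.0521), 41BB+ 72 h replicates 2 (0.102) or 3 (0.138) or 41BB- 72 h replicates 2 (0.0960) or 3 (0.0598).

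The inversion of the population difference between 0 h and 72 h (Spearman correlation across 10406 genes -0.602, genes not being independent) was weighed against 3 explanations. An exchange of labels at 72 h would turn the T cell receptor beta V segment usage around, but the 41BB+ to 41BB- usage ratios of 14 segments at 0 h and 72 h correlated positively (Pearson 0.649, BH-adjusted permutation p = 0.0387; Spearman 0.657, p = 0.0372; Pearson 0.560 without the 2 farthest segments; 3 pairs of times compared, the others at 0.192 and 0.136), which argues against it. Scaling by composition moves all genes of a library alike, so it is argued against by the order of 2 gene sets. At 72 h the median log2FC of the 2276 genes lower at 0 h lay 0.798 above that of the 2916 higher ones (0.573 to 1.03 over 9 pairs of 72 h libraries), a gap that no scaling factor changes. What stays open is that 41BB+ cells may have left the activated state earlier: the 72 h population difference correlated at -0.65 across genes with the 0 h to 24 h change of 41BB- cells, which shares no library with it.

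The many differences at 0 h could be a state like early activation, since they correlated at 0.442 across genes with the 24 h over 72 h change of 41BB- cells, and this stays open. A handling response is argued against in 41BB+ cells, with 8 of 12 immediate early genes lower (median log2FC -1.74), but open in 41BB- cells. In 41BB+ cells at 0 h list medians were 31.7 CPM for CD4 helper genes (some also of CD8 T cells) and 307 for CD8 identity. They were 0.557 to 3.20 CPM for B, dendritic, myeloid and NK cell genes. This argues against other cells as most of the 41BB+ sort, but a median cannot exclude a minor share. Itgax (62, 22 and 94 counts against 17, 19 and 12) and Csf1r were higher in 41BB+ libraries, Ighm lower.

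The genes Il31ra, Cmss1, Gphn and Camk1d had 785.4 to 3418 CPM in these T cell libraries. Reads of ribosomal RNA counted in them are a candidate explanation that stays open, as their levels within groups followed the annotated rRNA gene CT010467.1 over 18 libraries (median Pearson r 0.851). By gene, r was 0.847 for Il31ra (Spearman 0.802, 0.718 without the 2 farthest libraries), 0.856 for Cmss1 (0.804, 0.752), 0.857 for Gphn (0.796, 0.714) and 0.693 for Camk1d (0.676, 0.605), with BH-adjusted permutation p = 0.00015, 2e-04, 0.00015 and 0.00247 over 6 genes. The other 2, Zc3h7a (r -0.536, Spearman -0.534, -0.431 without the 2 farthest, p = 0.0287) and Cdk8 (0.213, 0.00929, 0.244, p = 0.396), did not follow it. With Gm23935, which lies within Zc3h7a, r was 0.943 for Zc3h7a (Spearman 0.932, 0.914, p = 3e-04), 0.114 for Cdk8 (0.278, 0.133, p = 0.656), -0.645 for Il31ra (-0.589, -0.342, p = 0.0072), -0.463 for Cmss1 (-0.406, -0.0983, p = 0.0739), -0.61 for Gphn (-0.544, -0.356, p = 0.0097) and -0.114 for Camk1d (-0.166, 0.215, p = 0.656). Library depth cannot be told apart as a part of this, since the median absolute r with total counts was 0.402.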

How the results depend on the processing

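The block within each time and the Y-linked covariate were chosen only after the data were seen. Of the values of named genes under alternatives 16103 kept their direction and side of the threshold, 536 lost the call, 45 gained it and 0 changed sign past the threshold, and of those of lists 3587 stayed, 152 lost and 135 gained it. The 1 reversal was the effector list from 0 h to 24 h in 41BB- cells, which fry placed up (adjusted p = 0.0284) and camera down, and whose median and mean differ in sign. Asking for at least 2-fold left 2725, 155 and 662 genes between populations at 0, 24 and 72 h, 2152 and 4236 for the first and second interval in 41BB+ cells, 4897 and 2765 in 41BB- cells, and 1871 and 1246 for the interactions, by its construction. The count at 24 h rose from 361 to 577 with the block within each time and to 550 with voom, and was 181 to 261 with 1 library left out, where fewer libraries are tested. With an estimated correlation 1, 1 and 0 lists were called between populations at 0, 24 and 72 h, 3 and 1 for the intervals in 41BB+ cells, 3 and 0 in 41BB- cells, and 1 and 0 for the interactions, since the estimated correlations were mostly above the preset. With fry, which tests each list by itself, the numbers were 21 and 2 between populations at 0 and 24 h, 24 and 23 for the intervals in 41BB+ cells, and 28 and 21 in 41BB- cells. Without the filter 17 lists passed in 41BB- cells from 24 h to 72 h, and with 1 library left out 5 to 9 lists passed at 24 h (5 without 41BB+ replicate 1). Genes called in the same direction at 24 h and 72 h were 23 with DESeq2, and with the block within each time the numbers were 349, 27 and 101 for 0 and 24 h, 24 and 72 h, and 0 and 72 h. The cause of these moves was not tested. Other counts stayed within 1.5 times when 1 library was left out, at 4471 to 4807 between populations at 0 h, 1840 to 2307 at 72 h, 3730 to 3949 and 6239 to 6560 in 41BB+ cells, 6752 to 7021 and 4679 to 4852 in 41BB- cells, and 2547 to 2914 and 1772 to 2315 for the interactions. With only the compared groups in the fit 49.8% of the genes called at 72 h were higher in 41BB+ cells, against 35.5%, and without the filter 50.8% at 24 h, against 60.9%. The replicate block across times changed no call of a named gene or list between populations other than those given in the text. At these depths 1.41-fold differences were mostly missed in simulated data, in which few genes were changed.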

Other observations

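The test of hypoxia genes was chosen only after the result it bears on was seen. The transcription factor gene Ikzf2 did not take part in the inversion. It was higher in 41BB+ cells at all 3 times (log2FC 1.53, 1.29 and 1.43) and rose between 24 h and 72 h in them (2.59).

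Genes induced by low oxygen outside glycolysis were lower in 41BB+ cells at 72 h in 14 of 23 cases (median log2FC -1.08; unadjusted camera p = 1.74e-07, and p = 0.0425 with an estimated correlation), such as Fam162a (-2.07), P4ha1 (-1.83) and Egln3 (-2.24). From 24 h to 72 h 13 rose in 41BB- cells (camera p = 0.000299, and p = 0.142 with an estimated correlation), while in 41BB+ cells 8 rose and 7 fell (camera p = 0.871). The lower glycolysis genes of 41BB+ cells at 72 h may therefore go with a weaker hypoxia response of their cultures, a hypothesis that stays open, since cell density and oxygen are not given in the sources used here.

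Transcripts of myeloid cells stood out in 1 pair of libraries. Lyz2 had 173 counts in 41BB+ 24 h replicate 2 and 29 in 41BB- 24 h replicate 2, Csf1r 41 and 8, and S100a8 16 and 0. Foxp3 had 70, 87 and 36 counts in 41BB+ and 30, 12 and 17 counts in 41BB- libraries 1 to 3 at 72 h.

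For each comparison of 3 against 3 libraries, 1 of 10 splits, the real one, gave as many genes, and 10 splits are too few for a share under 0.05. The real and the highest other counts were 5192 and 0 between populations at 0 h, 361 and 0 at 24 h, 2485 and 9 at 72 h, 4545 and 1 for 0 h to 24 h and 6903 and 0 for 24 h to 72 h in 41BB+ cells, and 7445 and 0 and 5366 and 0 for the same intervals in 41BB- cells.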
